A study of Mus musculus with 8 samples.

How the data were processed

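Small intestine was collected from 6-week-old female mice of 4 groups after 5 days of daily injection, snap frozen and used for total RNA, and biotin-labelled cRNA was hybridised to Affymetrix arrays. The intensity values were made by the authors with MAS5 and deposited as signal per probe set; the MAS5 version is not given in the sources used here. The labels describe the tissue only as small intestine and do not give the segment or the position along the gut for any sample. The replicate labels and the design text are the only statement on replicates, which give 2 mice per group, and nothing else in the labels says how replicates were made. The p-values therefore measure the spread between these arrays.

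The table held 22690 probe sets in 8 sample columns, and 0 columns were left unused. The 2 DBZ columns were identical in 22684 probe sets and differed in 6, so they were used as 1 array. The planned design of 2 DBZ arrays could not be kept, and the lone DBZ array was assumed to vary like the other groups. The table held no detection calls, and low signals rest on the pseudocount.

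Each array was scaled to a trimmed mean of 250, with 2% trimmed at each end. Values were taken as log2 of signal plus 12.46, the pooled 20th percentile. Probe sets with a mean signal under 39.14, the pooled 40th percentile, and 64 control probe sets were left out, which left 13637. Of all probe sets 20393 carried 1 gene symbol, 691 several and 1606 none in the table used here. The gene number of 20364 was found in the gene table, and 0 symbols were updated. Each of 8093 genes was represented in list tests by its probe set with the highest mean signal.

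A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, using moderated t tests with an intensity trend, 2-sided p and Benjamini-Hochberg adjustment at 0.05 over all tested probe sets. The residual degrees of freedom were 3 and the prior degrees of freedom 6.85. The comparisons were each treated group against vehicle, the combination against DBZ, the combination against dexamethasone, and the interaction, which is combination minus dexamethasone minus the difference of DBZ and vehicle. "Rose" and "fell" are used of genes past the threshold, and "call" of a gene or list past it. Values after ± are SE for log2 changes and SD for signals.

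Gene lists were fixed before the data were examined, 40 in number with 1033 members, of which 893 had a probe set named here and 670 were tested; 37 lists had at least 3 tested genes. They were tested with cameraPR at a preset correlation of 0.01 between genes and adjusted over 37 lists in each comparison. The same lists were tested with camera and an estimated correlation. That test rests on the 3 residual degrees of freedom and could miss true shifts. Counts adjusted over the list alone use only the list's genes. Of the lists, 26 passed in at least 1 comparison with the preset correlation and 11 in none. The median, mean and test differed in sign in 20 list results, of which 0 were past the threshold.

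The genes named were set by a rule written before the data were examined. It takes genes past the threshold with no overlap between the groups: the 10 largest rises and falls in DBZ against vehicle, dexamethasone against vehicle and the combination against DBZ, and the 5 largest in the other comparisons (for the interaction, without the condition on overlap). Anonymous symbols were passed over, and where fewer than 5 passed, the genes with the smallest p were named as not passing. To these were added Klf4, Ccnd2, Hes1, Atoh1, Muc2, Olfm4, Mki67, Fkbp5, Tsc22d3 and Nr3c1 in every comparison, and up to 4 members of each list described, by smallest p. Genes with more than 1 tested probe set were compared across them after the values were seen.

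The pipeline was tested on simulated data of 13637 probe sets with 200 changed. At a log2 change of 2 it recovered 54, 77 and 82% in DBZ, dexamethasone and the combination against vehicle. The combination against DBZ and dexamethasone gave 48 and 72%, and the interaction 0%. At a change of 1 the shares were 5, 20, 28, 2, 21 and 0%. Calls on unchanged probe sets were 1, 6, 10, 2, 1 and 0. A list of 19 goblet cell genes raised by 1 had adjusted p = 1.25e-32 (preset correlation) and 0.0682 (estimated). Its estimated correlation was 0.247 in the data, so this does not test preset calls.

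Alternatives fixed before the data were examined were the values as deposited, quantile normalisation, other pseudocounts and filters, other variance models, array weights, the removal of probe sets that may cross-hybridise, only the groups compared, a replicate block, and each array left out. Added after the values were seen were fits without the vehicle arrays, both DBZ columns as separate arrays, 1 vehicle array for each comparison, and the selection of probe sets used for the DBZ change with and without dexamethasone. Which lists were followed singly, and which genes were plotted, was also chosen after the values were seen. Random draws used seed 7.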

Results

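Gene expression was measured in small intestine of 6-week-old female C57/Black6 mice that received daily intraperitoneal injections for 5 days. The mice were given the vehicle dimethyl sulfoxide, the glucocorticoid dexamethasone at 15 mg/kg, the gamma-secretase inhibitor DBZ at 10 umol/kg, or both drugs together (the combination). Gamma-secretase releases the active intracellular part of Notch receptors, so DBZ blocks Notch signalling. The series concerns the pairing of gamma-secretase inhibitors with glucocorticoids against T-cell leukaemia, and the intestine is the tissue in which Notch blockade is known to convert progenitors into secretory goblet cells. Biotin-labelled RNA was hybridised to Affymetrix arrays of 22690 probe sets. The labels list 8 samples, 2 for each of 4 groups, but the pair of DBZ columns held identical values in 22684 probe sets and differed in 6, where 1 copy was listed at 0. No other pair of columns shared an identical value, so the DBZ columns were counted as 1 array and the data hold 7 distinct arrays, with n = 1 for DBZ and n = 2 for each other group. The small number of arrays limits the precision of every comparison.

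The vehicle arrays stood apart from all drug-treated arrays before any gene was tested. Their trimmed mean intensity as deposited was 500, against 250 in the 5 treated arrays, and all arrays were brought to 250 here. Spearman correlations between a vehicle array and a treated array ranged from 0.892 to 0.928, those between different treated groups from 0.939 to 0.972, and those within a group from 0.96 to 0.97. The signal of the probe set in the middle of 18S ribosomal RNA was 133 and 141 in the vehicle arrays and 29.9 to 64.7 in the treated arrays. The DBZ array had the highest ratios of signal at the 3' end to signal at the 5' end, a measure of RNA integrity, with 1.80 for Gapdh and 2.17 for beta-actin. The other arrays ranged from 0.905 to 1.22 for Gapdh and from 1.22 to 1.79 for beta-actin.

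Markers of intestinal position separated vehicle from every treated group. Fabp6, the bile acid binding protein of ileal enterocytes, had signals of 0.644 and 1.23 in the vehicle arrays, 3339 and 10080 with dexamethasone, 11960 with DBZ, and 1198 and 1125 with the combination. Reg1, a secreted protein of the regenerating family, had a mean signal of 7692 ± 643 (SD, n = 2) with vehicle, 78.0 ± 32.5 (SD, n = 2) with dexamethasone, 96.2 in the DBZ array and 84.9 ± 16.8 (SD, n = 2) with the combination. Slc46a1, the folate transporter of the proximal intestine, had 2663 ± 638, 263 ± 21.7, 526 and 627 ± 304 in the same order. The median log2 change of the ileal list exceeded that of the proximal list by 1.83 with DBZ, 2.14 with dexamethasone and 1.55 with the combination, each against vehicle. These differences accompany every comparison against vehicle.

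**Figure D1:**
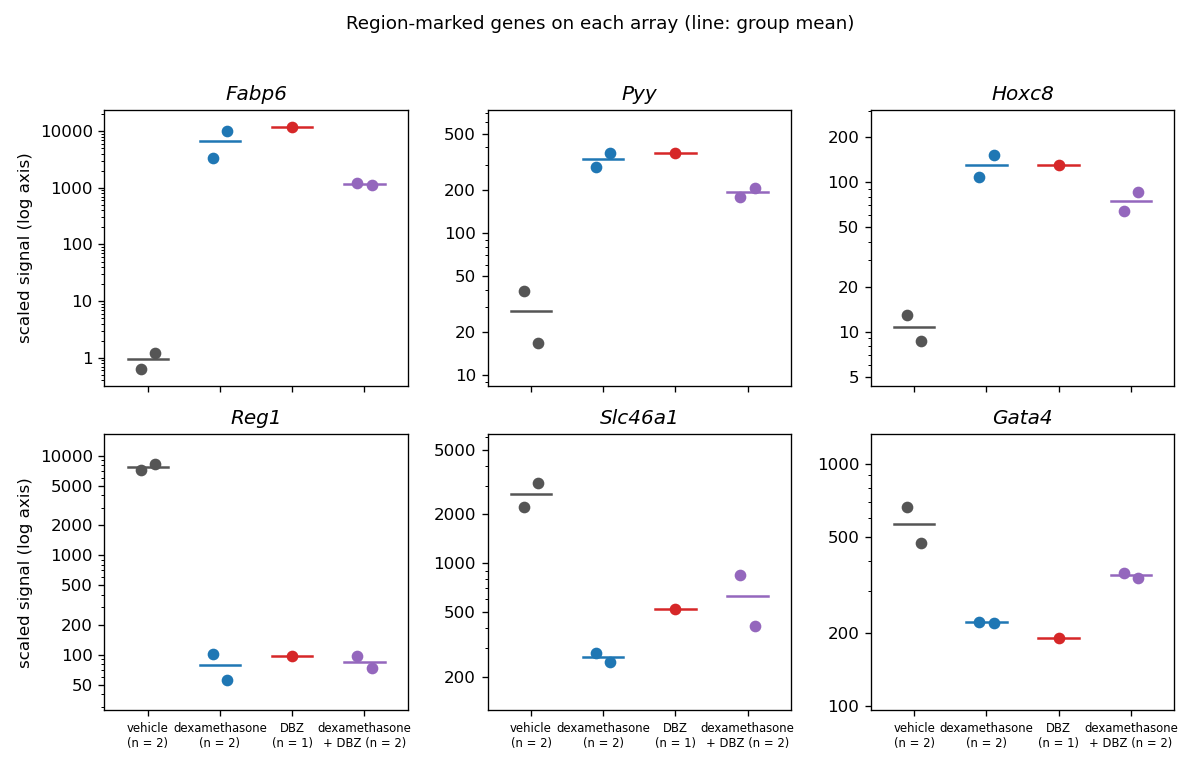
Scaled signal (log axis, arbitrary intensity units) of Fabp6, Pyy, Hoxc8, Reg1, Slc46a1 and Gata4 on each of the 7 arrays by treatment group, with a line at each group mean. Reg1 lies at 7238 and 8147 in the vehicle arrays and at 55.1 to 101 in the treated arrays; the genes shown were picked after their values had been seen.

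In DBZ against vehicle, Fabp6 had the largest rise and Reg1 the largest fall. Fabp6 rose by 9.80 ± 0.48 on the log2 scale (SE, 1 DBZ array against 2 vehicle arrays, adjusted p = 2.04e-05), a value set by the pseudocount because the vehicle arrays lay near the floor. Slc10a2, the ileal transporter that takes up bile acids, rose by 3.42 ± 0.58, and Pyy, the peptide hormone of distal enteroendocrine cells, rose by 3.28 ± 0.35. The transporters Slc34a2 (phosphate, 4.82 ± 0.72) and Slc5a8 (monocarboxylates, 4.53 ± 0.27) rose, as did Tmigd1 (5.16 ± 0.31), Fam151a (4.98 ± 0.48), Mgat4c (3.39 ± 0.45), the antibacterial lectin Reg3g (3.27 ± 0.76) and the sulfite oxidase Suox (3.19 ± 0.44). Among the falls, Reg1 changed by -6.14 ± 0.31, the intestinal alkaline phosphatase Akp3 by -3.39 ± 0.70, the cytochrome P450 Cyp2c29 by -3.03 ± 0.57, the carnitine-synthesis enzyme Bbox1 by -2.82 ± 0.42 and the alcohol dehydrogenase Adh4 by -2.75 ± 0.34. Slc4a5 (-2.88 ± 0.42), the endosomal GTPase Rab5c (-2.76 ± 0.21), the Myc partner Max (-2.75 ± 0.41), the nucleosome-binding protein Hmgn1 (-3.12 ± 0.23) and the splicing protein Snrpd3 (-2.90 ± 0.25) also fell. For Hmgn1 and Snrpd3 the other tested probe sets did not share the fall, with -0.04 and 0.19 for Hmgn1 and -0.03 for Snrpd3. Leaving out vehicle replicate 2 ended the calls of Reg3g (2.45) and Cyp2c29 (-2.69), and the call of Reg3g also ended without combination replicate 1 (3.26) or 2 (3.27).

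Of the genes fixed in advance for their part in Notch and glucocorticoid signalling, the glucocorticoid-induced Tsc22d3 rose in the DBZ array by 1.37 ± 0.35 (adjusted p = 0.041). Its other tested probe sets gave 0.79 and -0.16, and the call ended without vehicle replicate 1 (1.06), combination replicate 1 (1.37) or combination replicate 2 (1.37). The transcription factor Klf4, which marks goblet cell differentiation, had 0.79 ± 0.26 (adjusted p = 0.0955), the Notch target Hes1 -0.66 ± 0.34 (adjusted p = 0.255) and the secretory determinant Atoh1 0.10 ± 0.31 (adjusted p = 0.875), and none of them passed. Cyclin D2 (Ccnd2) had 0.27 ± 0.29, the proliferation marker Mki67 -0.88 ± 0.34, the glucocorticoid-induced chaperone Fkbp5 -0.06 ± 0.41 and the glucocorticoid receptor Nr3c1 -0.62 ± 0.20, and none passed. Over the 9 Notch target genes tested the median was -0.62, with 8 lower and 1 higher, adjusted p = 0.0527, and adjusted p = 0.504 with an estimated correlation. Limma called 0 of them over all probe sets and 2 lower adjusted over the list alone (3 at unadjusted p under 0.05), Notch3 (-1.32 ± 0.37) and Sox9 (-1.28 ± 0.38) having the smallest p.

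The G2/M and G1/S lists were lower in the DBZ array. All 32 tested genes of the list for G2/M and mitosis were lower, with a median of -1.20, and 12 fell (21 adjusted over the list alone; list adjusted p = 1.08e-11, adjusted p = 0.504 with an estimated correlation). The mitotic kinases Aurkb (-2.37 ± 0.41) and Plk1 (-1.82 ± 0.39) fell, as did the kinetochore protein Nuf2 (-2.35 ± 0.51) and the spindle checkpoint protein Mad2l1 (-1.68 ± 0.37). Of 27 genes for G1/S and DNA replication, 26 were lower, the median was -0.83 and 5 fell (13 adjusted over the list alone; list adjusted p = 1.95e-06, adjusted p = 0.517 with an estimated correlation). Uhrf1 stood at -1.36 ± 0.28 and Rrm1 at -1.49 ± 0.32. The ileal (1.46), smooth muscle (1.31) and fibroblast (1.03) lists shifted by similar amounts the other way in the same DBZ array, which had the highest 3' to 5' ratios (1.80 for Gapdh and 2.17 for beta-actin). Without vehicle replicate 1 the calls of Plk1 (-1.48), Nuf2 (-2.03), Mad2l1 (-1.36), Uhrf1 (-1.17) and Rrm1 (-1.23) ended.

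The goblet cell list had a median of 0.51 in DBZ against vehicle, with 18 of 19 genes higher, and 2 rose (3 adjusted over the list alone; list adjusted p = 0.000703, adjusted p = 0.504 with an estimated correlation). The median was -0.46 with the intensities as deposited, where the median of all probe sets was -1.0. Guanylin (Guca2a), which regulates intestinal fluid secretion and also stands on the ileal list, rose by 2.21 ± 0.25. The secreted Clca1 rose by 1.22 ± 0.29, a call that ended without vehicle replicate 1 (1.34) or 2 (1.10), and its other probe set gave 0.36. Ern2, the endoplasmic reticulum stress sensor of goblet cells, had 1.52 ± 0.42 and did not pass (adjusted p = 0.0528). The mucin Muc2 and the stem cell marker Olfm4 were fixed for naming but were not analysed here.

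Lists of muscle, connective tissue and the distal intestine were higher with DBZ than with vehicle. Of 18 ileal genes 11 rose and 0 fell (14 and 2 adjusted over the list alone; 16 at unadjusted p under 0.05 by limma), the median was 1.46 and the list adjusted p was 7.86e-19. The metalloprotease Mep1a rose by 2.86 ± 0.23. Of 20 proximal genes 7 fell and 1 rose (7 and 2 adjusted over the list alone; median -0.37, list adjusted p = 0.00168), among them the protease Ctse (-2.33 ± 0.26, its other probe set -0.48) and, in the other direction, the carotenoid-cleaving enzyme Bco1 (2.72 ± 0.35). All 16 smooth muscle genes were higher, with a median of 1.31, and 9 rose (13 adjusted over the list alone; list adjusted p = 5.19e-11). Transgelin (Tagln) stood at 1.52 ± 0.26. Of 29 fibroblast and matrix genes 27 were higher, the median was 1.03 and 9 rose (17 adjusted over the list alone; list adjusted p = 1.80e-09), with 0.57 without vehicle replicate 2. The BMP antagonist Grem1 stood at 2.02 ± 0.27. For each of these 4 lists, adjusted p = 0.504 with an estimated correlation.

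In DBZ against vehicle, 13 of 38 genes of xenobiotic metabolism fell and 1 rose (16 and 2 adjusted over the list alone; median -0.54, list adjusted p = 1.38e-06). The glucuronosyltransferase Ugt2b5 stood at -2.49 ± 0.28. Of 19 cholesterol synthesis genes 5 rose (6 adjusted over the list alone; median 0.47, -0.51 as deposited, list adjusted p = 2.19e-05). Squalene epoxidase (Sqle) stood at 1.90 ± 0.25. Of 38 glucocorticoid receptor targets 9 rose (10 and 1 lower adjusted over the list alone; median 0.34, -0.62 as deposited, list adjusted p = 0.000105). Map3k6 stood at 2.23 ± 0.27 and Txnip at 1.60 ± 0.21. For these 3 lists adjusted p = 0.504 with an estimated correlation. Of 11 T cell genes 3 fell and 1 rose (the same counts adjusted over the list alone; median -0.67, list adjusted p = 0.0183, adjusted p = 0.583 with an estimated correlation), the granule proteases Gzmb (-2.43 ± 0.28) and Gzma (-1.82 ± 0.22) among them. The T cell list no longer passed as deposited (-1.20) or without a filter (-0.28), and had -0.43 without combination replicate 1. All 6 genes of MHC class II presentation were higher (median 0.90, -0.09 as deposited), and the invariant chain Cd74 rose by 1.23 ± 0.32 (1 gene, and 4 adjusted over the list alone; list adjusted p = 0.0121, adjusted p = 0.504 with an estimated correlation). The call of Cd74 ended without vehicle replicate 2 (0.95) or either combination array (1.23 for each), and the median of its list was 0.54 without vehicle replicate 2.

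In the other 5 lists past the threshold in DBZ against vehicle, the call or the sign changed when a single array was left out. The interferon list (median -0.58, 2 of 24 fell, 9 lower and 1 higher adjusted over the list alone, adjusted p = 0.526 with an estimated correlation) no longer passed without vehicle replicate 1 (-0.51). Its proteasome subunit Psmb8 stood at -1.21 ± 0.22. The immediate early list (median 0.55, -0.43 as deposited, 2 of 23 rose, 2 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation; Hspa1b 1.71 ± 0.33) and the apoptosis and p53 list (median 0.09, -0.86 as deposited, 4 of 18 rose, 4 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation) did not pass without that array either (0.44 and 0.11). The apoptosis median was 0.25 without vehicle replicate 2. In that list the pro-apoptotic Bcl2l11 rose by 2.37 ± 0.24, while its other probe sets gave 0.45, -0.67 and -0.11. The pancreatic acinar list (median -0.81, 1 of 5 fell, 2 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation) no longer passed without vehicle replicate 2 (-0.67). It had -1.42 without vehicle replicate 1, -1.26 without dexamethasone replicate 2 and -1.23 without either combination array. The antimicrobial list (median -0.18, 4 of 15 fell and 2 rose, 5 and 2 adjusted over the list alone, adjusted p = 0.851 with an estimated correlation) turned to 0.22 without vehicle replicate 1 and to 0.16 without replicate 2, and had -0.33 without dexamethasone replicate 1; Reg1 fell and the protease inhibitor Slpi rose (2.51 ± 0.34).

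Limma called 1137 of 13637 tested probe sets in DBZ against vehicle, 512 higher and 625 lower, with 3590 at unadjusted p under 0.05. With the intensities as deposited the split was 126 higher and 9390 lower, and with quantile normalisation it was 553 and 526. Without a filter 540 probe sets were called and without the intensity trend 684. Of 37 lists 17 passed with the preset correlation and 0 with the estimated correlation (camera; 2 at unadjusted p under 0.05). The count of probe sets was 723 (442 higher and 281 lower) without vehicle replicate 1, 708 without combination replicate 1 and 700 without combination replicate 2.

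In dexamethasone against vehicle, Fabp6 had the largest rise and Reg1 the largest fall. Fabp6 rose by 8.76 ± 0.39 (SE, n = 2 per group, adjusted p = 6.03e-06), Tmigd1 by 4.58 ± 0.25, Fam151a by 4.40 ± 0.39, Mgat4c by 4.07 ± 0.36, Slc5a8 by 3.98 ± 0.22, Slc34a2 by 3.77 ± 0.59, Pyy by 3.12 ± 0.28, Slc10a2 by 3.0 ± 0.48 and the acyltransferase Mboat1 by 2.97 ± 0.48. The stress-induced regulator Nupr1 rose by 3.52 ± 0.64, a call that ended without vehicle replicate 2 (2.87). Reg1 changed by -6.46 ± 0.25, Cyp2c29 by -6.42 ± 0.46 and alpha-fetoprotein (Afp) by -4.55 ± 0.36. The lectin-like Clec2d (-3.60 ± 0.39), Akp3 (-3.53 ± 0.57), Bbox1 (-3.39 ± 0.34), Slc46a1 (-3.26 ± 0.30), Adh4 (-3.03 ± 0.28), the carboxylesterase Ces2g (-2.96 ± 0.18) and Max (-2.76 ± 0.34) fell as well.

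Classical glucocorticoid-induced genes did not move together in the dexamethasone arrays. Fkbp5, which glucocorticoids induce in many tissues, changed by -1.78 ± 0.34 (adjusted p = 0.00967), from a signal of 1142 ± 260 with vehicle to 338 ± 160 with dexamethasone (SD, n = 2 each), and the call ended without vehicle replicate 2 (-1.55). Pdk4, the kinase that limits pyruvate oxidation, changed by -2.32 ± 0.25, while Map3k6 (1.90 ± 0.22) and Txnip (1.23 ± 0.17) rose. Of 38 glucocorticoid receptor targets 8 rose and 5 fell (10 and 6 adjusted over the list alone), the median was -0.25 and the list did not pass (adjusted p = 0.867, adjusted p = 0.958 with an estimated correlation). Tsc22d3 had -0.27 ± 0.28 and Nr3c1 -0.06 ± 0.17, and neither passed. Ccnd2 rose by 1.21 ± 0.24 (adjusted p = 0.0119), a call that ended without dexamethasone replicate 2 (1.04) or vehicle replicate 2 (0.89). Klf4 (0.44 ± 0.22), Atoh1 (0.83 ± 0.25, adjusted p = 0.0601), Hes1 (0.19 ± 0.28) and Mki67 (-0.19 ± 0.28) did not pass. Limma called 0 of 32 genes for G2/M and mitosis (0 at unadjusted p under 0.05), and the list had a median of 0.02 while its test pointed down (adjusted p = 0.965). It also called 0 of 27 genes for G1/S and DNA replication (3 at unadjusted p under 0.05; median -0.06, adjusted p = 0.531).

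**Figure D2:**
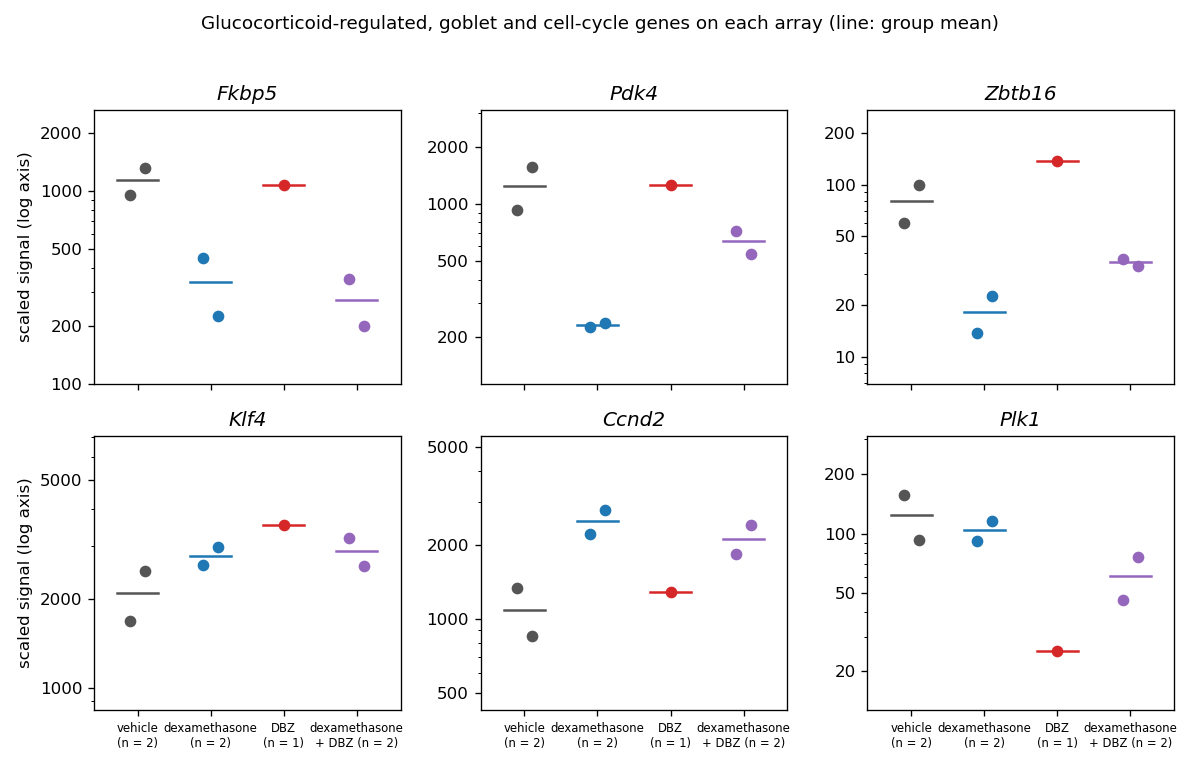
Scaled signal (arbitrary intensity units) of Fkbp5, Pdk4, Zbtb16, Klf4, Ccnd2 and Plk1 on each of the 7 arrays by treatment group, with a line at each group mean. Fkbp5 has a mean of 1142 with vehicle, 338 with dexamethasone, 1080 in the DBZ array and 274 with the combination; Fkbp5, Klf4 and Ccnd2 were fixed for naming before the data were examined and the other genes shown were picked after their values had been seen.

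The goblet and Paneth cell lists were higher with dexamethasone than with vehicle. The tuft cell (median -0.72, adjusted p = 0.167), enteroendocrine (adjusted p = 0.746) and secretory specification lists (median 0.03, adjusted p = 0.5355) did not pass. Of 19 goblet cell genes 17 were higher and 7 rose (11 adjusted over the list alone; median 0.73, -0.22 as deposited, list adjusted p = 1.49e-05, adjusted p = 0.438 with an estimated correlation). Guca2a rose by 2.20 ± 0.20. Ern2 (1.72 ± 0.34) and the disulfide isomerase Agr2 (1.25 ± 0.28) rose, but both calls ended without dexamethasone replicate 1 (1.5 and 1.06) or vehicle replicate 2 (1.15 and 1.0). Of 8 Paneth cell genes 5 rose (5 adjusted over the list alone; median 1.02, list adjusted p = 0.00167, adjusted p = 0.438 with an estimated correlation), led by the mucosal pentraxin Mptx1 (1.96 ± 0.30) and Nupr1, but the list no longer passed with a filter at the 60th percentile (0.90). Beside these, the ileal list had a median of 1.35 (10 of 18 rose, 11 and 1 lower adjusted over the list alone, list adjusted p = 2.49e-16, adjusted p = 0.438 with an estimated correlation; 2.30 without vehicle replicate 1). The proximal list had -0.80 (10 of 20 fell and 1 rose, 13 and 2 adjusted over the list alone, list adjusted p = 4.90e-13, adjusted p = 0.154 with an estimated correlation), with Slc46a1 and the vitamin A binding protein Rbp2 (-1.80 ± 0.18) among the falls.

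In dexamethasone against vehicle, 25 of 38 xenobiotic metabolism genes fell and 1 rose (25 and 2 adjusted over the list alone; median -0.999, list adjusted p = 5.34e-23, adjusted p = 0.154 with an estimated correlation), among them Cyp2c29, Cyp3a25 (-2.51 ± 0.22) and Cyp2b10 (-1.78 ± 0.17). Of 19 genes of glucose handling 8 fell (10 and 1 higher adjusted over the list alone; median -0.51, list adjusted p = 6.89e-05), with Pdk4 and the gluconeogenic enzyme Pck1 (-1.50 ± 0.21). Of 29 genes of fatty acid oxidation 7 fell (10 and 1 higher adjusted over the list alone; median -0.30, -0.17 without dexamethasone replicate 1, list adjusted p = 0.00111). All 19 cholesterol synthesis genes were higher and 8 rose (9 adjusted over the list alone; median 0.62, -0.33 as deposited, list adjusted p = 2.00e-08). Sqle stood at 2.09 ± 0.20. For these 3 lists adjusted p = 0.438 with an estimated correlation. Of 30 absorptive enterocyte genes 8 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.30, adjusted p = 0.655 with an estimated correlation). Apolipoprotein B (Apob) stood at -2.33 ± 0.29. The urea cycle list had -0.57 (4 of 13 fell and 1 rose, 5 and 1 adjusted over the list alone, adjusted p = 0.655 with an estimated correlation). The enterocyte list no longer passed with quantile normalisation (-0.18) or without dexamethasone replicate 1 (-0.16) or vehicle replicate 2 (-0.21). Nor did the urea cycle list without dexamethasone replicate 1 (-0.17), vehicle replicate 1 (-0.45), the intensity trend (-0.57) or probe sets that may cross-hybridise (-0.57). Intestinal steroid metabolism did not pass (median 0.60, 3 of 8 rose and 1 fell, adjusted p = 0.674).

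All 16 smooth muscle genes were higher with dexamethasone than with vehicle and 13 rose (14 adjusted over the list alone; median 1.19, list adjusted p = 3.66e-11, adjusted p = 0.438 with an estimated correlation). Of 29 fibroblast genes 16 rose (21 and 1 lower adjusted over the list alone; median 1.13, 0.60 without vehicle replicate 2, list adjusted p = 1.45e-10, adjusted p = 0.441 with an estimated correlation). Periostin (Postn) stood at 2.03 ± 0.21. All 11 adipose genes were higher and 4 rose (5 adjusted over the list alone; median 1.35, list adjusted p = 0.00228, adjusted p = 0.452 with an estimated correlation), but the calls of lipoprotein lipase (Lpl, 2.33 ± 0.48) and Plin4 (1.38 ± 0.32) ended without dexamethasone replicate 1 (2.20 and 1.03), and that of Plin4 also without vehicle replicate 2 (0.97). The adipose median was 2.30 without vehicle replicate 1 and 0.60 without replicate 2. Of 11 T cell genes 3 fell and 1 rose (the same counts adjusted over the list alone; median -0.76, list adjusted p = 0.00132, adjusted p = 0.438 with an estimated correlation). The list no longer passed as deposited (-1.66) and had -0.50 without dexamethasone replicate 1 and -1.28 without replicate 2. The chemokine Ccl5 stood at -1.89 ± 0.25. Of 24 interferon genes 8 fell and 1 rose (the same counts adjusted over the list alone; median -0.50, adjusted p = 0.582 with an estimated correlation). Of 15 B cell genes 13 were lower and 2 fell (2 adjusted over the list alone; median -0.48, list adjusted p = 0.039, adjusted p = 0.438 with an estimated correlation), the immunoglobulin joining chain Jchain at -1.19 ± 0.26 and the transcription factor Spib at -1.31 ± 0.28. The calls of Jchain and Spib ended without dexamethasone replicate 1 (-0.95 and -1.23), that of Jchain without vehicle replicate 1 (-0.85) and that of Spib without vehicle replicate 2 (-1.19). The B cell list no longer passed without dexamethasone replicate 2 (-0.48), vehicle replicate 2 (-0.22), the DBZ array (-0.29) or combination replicate 2 (-0.54), nor the interferon list without dexamethasone replicate 2 (-0.24) or vehicle replicate 1 (-0.48).

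Limma called 1634 of 13637 probe sets in dexamethasone against vehicle, 976 higher and 658 lower (3658 at unadjusted p under 0.05). With the intensities as deposited, where the median of all probe sets was -0.92, the split was 196 higher and 10207 lower. Without a filter 1079 probe sets were called. Of 37 lists 16 passed with the preset correlation and 0 with the estimated correlation (camera; 2 at unadjusted p under 0.05). The count of probe sets was 572 without dexamethasone replicate 1, 1023 without dexamethasone replicate 2 and 744 without vehicle replicate 2.

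In the combination against vehicle, Fabp6 had the largest rise and Reg1 the largest fall. Fabp6 rose by 6.45 ± 0.39 (SE, n = 2 per group, adjusted p = 5.71e-05), Slc34a2 by 4.70 ± 0.59, Tmigd1 by 4.25 ± 0.25, Fam151a by 4.18 ± 0.39 and Slc5a8 by 3.78 ± 0.22. Reg1 changed by -6.31 ± 0.25, Afp by -3.92 ± 0.36, Cyp2c29 by -3.59 ± 0.46 and Clec2d by -2.93 ± 0.39. The calcium-binding protein S100g of duodenal enterocytes changed by -3.57 ± 0.79 (adjusted p = 0.0251), a call that ended without vehicle replicate 1 (-3.86) or 2 (-3.31) or combination replicate 1 (-3.53) or 2 (-3.59). Fkbp5 changed by -2.04 ± 0.34 (adjusted p = 0.0081) and Ccnd2 by 0.98 ± 0.24 (adjusted p = 0.0383; -0.02 as deposited). The call of Fkbp5 ended without vehicle replicate 2 (-1.81) or combination replicate 2 (-1.66), and that of Ccnd2 without vehicle replicate 2 (0.65) or combination replicate 1 (1.17) or 2 (0.78). Klf4 (0.49 ± 0.22), Hes1 (-0.34 ± 0.28), Atoh1 (0.28 ± 0.25), Mki67 (-0.54 ± 0.28), Tsc22d3 (0.81 ± 0.28) and Nr3c1 (0.27 ± 0.17) did not pass.

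In the combination against vehicle, 8 of 18 ileal genes rose (12 and 2 lower adjusted over the list alone; median 1.23, list adjusted p = 6.32e-15). The proximal list had a median of -0.31 and did not pass (5 of 20 fell and 1 rose, 7 and 3 adjusted over the list alone, adjusted p = 0.118, adjusted p = 0.569 with an estimated correlation). Of 29 fibroblast genes 8 rose (13 adjusted over the list alone; median 0.62, -0.31 as deposited, 1.07 without vehicle replicate 1, 0.32 without replicate 2, list adjusted p = 1.37e-08). Lumican (Lum) stood at 1.85 ± 0.18. Of 16 smooth muscle genes 8 rose (12 adjusted over the list alone; median 0.88, -0.11 as deposited, list adjusted p = 1.37e-08), and the call of Tagln (1.15 ± 0.21) ended without vehicle replicate 2 (0.93) or combination replicate 1 (1.25) or 2 (1.05). Of 38 xenobiotic metabolism genes 13 fell and 1 rose (19 and 2 adjusted over the list alone; median -0.48, list adjusted p = 1.37e-08). Of 19 cholesterol synthesis genes 6 rose (7 adjusted over the list alone; median 0.45, -0.54 as deposited, list adjusted p = 1.7e-06). For these lists past the threshold adjusted p = 0.569 with an estimated correlation.

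Of 27 genes for G1/S and DNA replication 26 were lower with the combination than with vehicle and 3 fell (6 adjusted over the list alone; median -0.57, list adjusted p = 5.29e-05, adjusted p = 0.652 with an estimated correlation). The median was -0.31 without combination replicate 1 and -0.89 without replicate 2. The licensing factor Cdt1 fell (-0.997 ± 0.20), a call that ended without vehicle replicate 2 (-0.92) or combination replicate 1 (-0.77) or 2 (-1.22). All 32 genes for G2/M and mitosis were lower, with a median of -0.55 (-1.48 as deposited), but limma called 0 of them over all probe sets and 0 adjusted over the list alone (12 at unadjusted p under 0.05; list adjusted p = 0.000188, adjusted p = 0.678 with an estimated correlation), and the list no longer passed without vehicle replicate 1 (-0.31) or combination replicate 1 (-0.24); it had -0.91 without combination replicate 2. The goblet cell list had a median of 0.39 (-0.54 as deposited, 0.18 without combination replicate 2), with 17 of 19 genes higher and 2 risen (4 adjusted over the list alone; list adjusted p = 0.000188, adjusted p = 0.569 with an estimated correlation). The 38 glucocorticoid receptor targets had a median of 0.12 and did not pass (4 rose and 1 fell, 8 and 7 adjusted over the list alone, adjusted p = 0.133, adjusted p = 0.707 with an estimated correlation), although Map3k6 (2.02 ± 0.22), the metallothionein Mt2 (1.74 ± 0.23) and Txnip (1.21 ± 0.17) rose. The 9 Notch targets had a median of -0.36 and did not pass (adjusted p = 0.291, adjusted p = 0.569 with an estimated correlation).

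Of 11 T cell genes 4 fell and 1 rose with the combination against vehicle (6 and 1 adjusted over the list alone; median -1.02, -0.52 without combination replicate 1, list adjusted p = 0.000188), and the list no longer passed as deposited (-1.89). Of 24 interferon genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.54, list adjusted p = 3.99e-05). Of 23 immediate early genes 7 rose (7 and 1 lower adjusted over the list alone; median 0.37, -0.57 as deposited, list adjusted p = 0.0033), and the list no longer passed without vehicle replicate 1 (0.12) and had 0.20 without combination replicate 1. Of 19 genes of glucose handling 1 fell (6 adjusted over the list alone; median -0.27, list adjusted p = 0.0379), and the list no longer passed without vehicle replicate 2 (-0.29) or combination replicate 2 (-0.30). For these 4 lists adjusted p = 0.569 with an estimated correlation. Of 15 antimicrobial genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.18, list adjusted p = 0.000188, adjusted p = 0.678 with an estimated correlation). The immunoglobulin transporter Pigr stood at -1.57 ± 0.18. The antimicrobial list no longer passed without vehicle replicate 1 (-0.03), and it had -0.60 without vehicle replicate 2, -0.44 without dexamethasone replicate 1, -0.28 without combination replicate 1 and -0.32 without replicate 2. The B cell list did not pass (median -0.03, adjusted p = 0.918).

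Limma called 1023 of 13637 probe sets in the combination against vehicle, 606 higher and 417 lower (3297 at unadjusted p under 0.05). With the intensities as deposited, where the median of all probe sets was -0.98, the split was 127 higher and 10924 lower. Without a filter 623 probe sets were called and without the intensity trend 659. Of 37 lists 13 passed with the preset correlation and 0 with the estimated correlation (camera; 1 at unadjusted p under 0.05). The count of probe sets was 464 without vehicle replicate 2, 184 without combination replicate 1 and 170 without combination replicate 2.

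The 3 comparisons against vehicle overlapped widely, with 285 probe sets higher in all of them, 169 lower in all and 1 mixed. DBZ and dexamethasone shared 382 higher and 258 lower probe sets, where independent lists would share 36.6 and 30.2, and 1 was opposite. DBZ and the combination shared 308 and 215 (22.8 and 19.1 for independent lists, 2 opposite), and dexamethasone and the combination 496 and 270 (43.4 and 20.1, 0 opposite). Because the same vehicle arrays enter each comparison, 50 data sets with no true change were simulated, and their Pearson correlations were 0.408, 0.405 and 0.50 against 0.69, 0.727 and 0.798 in the data. The covariances were 0.279, 0.262 and 0.264 in the data and 0.0443, 0.0439 and 0.0445 in the simulations. With 1 vehicle array for each comparison, so that none was shared, the correlations were 0.43 and 0.595, 0.484 and 0.556, and 0.512 and 0.625 for the 2 ways to assign the arrays, and the covariances lay between 0.20 and 0.254. Part of the shared change may still come from what both vehicle arrays have in common.

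Adding dexamethasone to DBZ was followed by few calls. By their representative probe sets, 6 genes rose and 3 fell in the combination against DBZ (SE from 2 combination arrays against 1 DBZ array). The rises were Hmgn1 (2.95 ± 0.23, adjusted p = 0.00217), the gastric and duodenal protease Ctse (1.85 ± 0.25), Snrpd3 (1.74 ± 0.25), the Myc antagonist Mxd1 (1.65 ± 0.27), the transcription factor Gata6 (1.27 ± 0.20) and the splicing factor Srsf2 (1.22 ± 0.21). The falls were Fabp6 (-3.35 ± 0.48), clusterin (Clu, -1.53 ± 0.25) and the lysosomal sialidase Neu1 (-1.35 ± 0.23). Other genes were called by a further probe set alone, among them Tfrc (2.56), Sgpl1 (2.35), Rrm1 (1.90) and, in the other direction, Reg3b (-2.67, adjusted p = 0.0473). For Hmgn1, Ctse, Snrpd3, Gata6 and Srsf2 the other tested probe sets did not share the rise, with 0.19 and -0.14 for Hmgn1, -0.13 for Ctse, -0.41 for Snrpd3, 0.33 for Gata6 and 0.23, -0.34 and -0.05 for Srsf2. All 9 calls ended without combination replicate 2, for instance Hmgn1 at 2.77 and Fabp6 at -3.31, and all but that of Hmgn1 ended without combination replicate 1, for instance Fabp6 at -3.40. The calls of Mxd1, Gata6, Srsf2 and Neu1 also ended when any vehicle or dexamethasone array was left out (for instance 1.66, 1.27, 1.22 and -1.35 without vehicle replicate 1). Those of Snrpd3 (1.75) and Fabp6 (-3.35) ended without either vehicle array, and that of Clu (-1.53) without either dexamethasone array. All but that of Hmgn1 ended as deposited, with quantile normalisation or without a filter, and all 9 ended without the intensity trend. The DBZ array was the lowest of 7 in 36 of the 45 called probe sets and the highest in 3.

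None of the genes fixed in advance passed in the combination against DBZ. Fkbp5 had -1.98 ± 0.41 (adjusted p = 0.0932), with 1080 in the DBZ array and 274 ± 106 with the combination (SD, n = 2), and Nr3c1 had 0.89 ± 0.20 (adjusted p = 0.123). Klf4 (-0.30 ± 0.26), Ccnd2 (0.71 ± 0.29, adjusted p = 0.373), Hes1 (0.32 ± 0.34), Atoh1 (0.18 ± 0.31), Mki67 (0.33 ± 0.34) and Tsc22d3 (-0.56 ± 0.35) did not pass. The goblet cell list had a median of -0.13 (0 of 19 called, 0 at unadjusted p under 0.05 by limma, adjusted p = 0.721, adjusted p = 0.974 with an estimated correlation) and the Notch targets had 0.32 (0 of 9 called, 2 at unadjusted p under 0.05, adjusted p = 0.134, adjusted p = 0.733 with an estimated correlation).

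Mitotic genes were higher in the combination than in the DBZ array as a list. The G2/M list had a median of 0.62 with 30 of 32 genes higher, while limma called 0 over all probe sets and 0 adjusted over the list alone (11 at unadjusted p under 0.05; list adjusted p = 1.17e-08, adjusted p = 0.765 with an estimated correlation), and Aurkb had 1.46 ± 0.41 (adjusted p = 0.19). The G2/M median was 1.04 without combination replicate 1 and 0.24 without replicate 2. The 38 glucocorticoid receptor targets had a median of -0.33 with 28 lower (0 called, 6 lower and 1 higher adjusted over the list alone, 12 at unadjusted p under 0.05; list adjusted p = 0.000242, adjusted p = 0.643 with an estimated correlation), Zbtb16 having -1.64 ± 0.40 (adjusted p = 0.152). All 6 genes of MHC class II presentation were lower (median -0.90, 0 called, 4 adjusted over the list alone, 4 at unadjusted p under 0.05; list adjusted p = 0.000464, adjusted p = 0.643 with an estimated correlation). H2-Ab1 stood at -1.40 ± 0.41. Beside these, the ileal list had -0.30 (-0.45 without combination replicate 2; 1 of 18 fell, 5 adjusted over the list alone, list adjusted p = 0.000464, adjusted p = 0.765 with an estimated correlation) and the proximal list 0.16 (1 of 20 rose, 1 adjusted over the list alone, list adjusted p = 0.011, adjusted p = 0.643 with an estimated correlation), which no longer passed without probe sets that may cross-hybridise (0.13) or with the mean of all probe sets of a gene (0.14).

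The other 4 lists past the threshold in the combination against DBZ had 0 called genes and depended on single arrays. The smooth muscle list (median -0.35, 0 adjusted over the list alone, 2 of 16 at unadjusted p under 0.05 by limma, adjusted p = 0.915 with an estimated correlation) no longer passed without combination replicate 2 (-0.09). Nor did the Paneth cell list (median 0.70, 2 adjusted over the list alone, 2 of 8 at unadjusted p under 0.05, adjusted p = 0.765 with an estimated correlation; 0.25 without that array). The tuft cell list (median -0.78, 1 lower adjusted over the list alone, 4 of 7 at unadjusted p under 0.05, adjusted p = 0.643 with an estimated correlation) no longer passed without vehicle replicate 2 (-0.84) or combination replicate 2 (-0.69). The B cell list (median -0.43, 0 adjusted over the list alone, 5 of 15 at unadjusted p under 0.05, adjusted p = 0.643 with an estimated correlation) no longer passed without vehicle replicate 2 (-0.42).

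Limma called 45 of 13637 probe sets in the combination against DBZ, 41 higher and 4 lower (1681 at unadjusted p under 0.05). It called 8 with the intensities as deposited, 6 with quantile normalisation, 10 with a pseudocount at the 40th percentile, 5 without a filter, 0 without the intensity trend and 207 (156 higher and 51 lower) with only the groups compared. Of 37 lists 9 passed with the preset correlation and 0 with the estimated correlation (camera; 1 at unadjusted p under 0.05). The count was 29 without dexamethasone replicate 2, 22 without either vehicle array, 1 without combination replicate 1 and 0 without combination replicate 2.

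Adding DBZ to dexamethasone was followed by calls in 3 genes. In the combination against dexamethasone (n = 2 per group), the histone gene H2bc22 rose by 2.38 ± 0.28, the xenobiotic-metabolising Cyp2b10 rose by 1.31 ± 0.17 and the pentraxin Mptx1 changed by -2.42 ± 0.30, each with adjusted p = 0.0498. These calls ended without dexamethasone replicate 1 (2.63, 1.21 and -2.69), combination replicate 1 (2.49, 1.23 and -2.28) or combination replicate 2 (2.25, 1.38 and -2.55). The deacetylase Aadac (1.21 ± 0.16, adjusted p = 0.0507) and Neu1 (-1.36 ± 0.19, adjusted p = 0.0628) came next and did not pass. Klf4 (0.05 ± 0.22), Ccnd2 (-0.23 ± 0.24), Hes1 (-0.53 ± 0.28), Atoh1 (-0.55 ± 0.25), Mki67 (-0.36 ± 0.28), Fkbp5 (-0.27 ± 0.34), Tsc22d3 (1.08 ± 0.28, adjusted p = 0.275) and Nr3c1 (0.33 ± 0.17) did not pass either.

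Of 20 proximal genes 18 were higher in the combination than with dexamethasone and 1 rose (12 adjusted over the list alone; median 0.64, list adjusted p = 8.48e-23, adjusted p = 0.09 with an estimated correlation). The incretin Gip stood at 1.33 ± 0.20 (adjusted p = 0.063). Of 38 xenobiotic metabolism genes 1 rose (15 higher and 2 lower adjusted over the list alone; median 0.46, list adjusted p = 1.24e-15, adjusted p = 0.159 with an estimated correlation). Of 30 absorptive enterocyte genes 28 were higher (median 0.35, 0.20 without dexamethasone replicate 1, 0 called, 5 adjusted over the list alone, 12 at unadjusted p under 0.05 by limma; list adjusted p = 4.92e-13). Apob stood at 1.66 ± 0.29 (adjusted p = 0.104). All 32 G2/M genes were lower (median -0.65, -0.31 without combination replicate 1 and -0.97 without replicate 2, 0 called, 0 adjusted over the list alone, 13 at unadjusted p under 0.05 by limma; list adjusted p = 3.19e-09). The G1/S list had -0.48 (-0.16 without combination replicate 1 and -0.73 without replicate 2; 0 of 27 called, 3 adjusted over the list alone, 9 at unadjusted p under 0.05; list adjusted p = 8.53e-07) and the crypt base list -0.35 (0 of 16 called, 0 adjusted over the list alone, 6 at unadjusted p under 0.05; list adjusted p = 0.00388), which no longer passed without dexamethasone replicate 1 (-0.25) and had -0.57 without combination replicate 2. For the last 4 lists adjusted p = 0.495 with an estimated correlation. Cholesterol synthesis (median -0.22, 15 of 19 lower, adjusted p = 0.058), the urea cycle (median 0.12, adjusted p = 0.0553) and intestinal steroid metabolism (median -0.18, adjusted p = 0.9775) did not pass.

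Among the remaining lists of the combination against dexamethasone, the glucocorticoid receptor targets had 0.05 (0.03 without dexamethasone replicate 1, 0.20 without dexamethasone replicate 2, 0.09 without combination replicate 2; 0 of 38 called, 6 adjusted over the list alone, 12 at unadjusted p under 0.05 by limma; list adjusted p = 0.0022). The antimicrobial list had -0.70 (-0.25 without dexamethasone replicate 1 and -1.21 without replicate 2; 0 of 15 called, 8 lower and 1 higher adjusted over the list alone, 9 at unadjusted p under 0.05; list adjusted p = 0.000357). Reg3b stood at -2.44 ± 0.53 (adjusted p = 0.196). Lists that a single array decided were Paneth cell (-0.74, 1 of 8 fell, 4 and 1 higher adjusted over the list alone; -0.38 without combination replicate 1), B cell (0.25, 0 of 15 called, 2 adjusted over the list alone, 6 at unadjusted p under 0.05; 0.26 without dexamethasone replicate 2, 0.46 without replicate 1, 0.49 without combination replicate 1) and glucose handling (0.18, 0 of 19 called, 2 adjusted over the list alone, 6 at unadjusted p under 0.05; 0.14 without dexamethasone replicate 1, 0.38 without replicate 2, 0.30 without combination replicate 2). So were adipose tissue (-1.17, 0 of 11 called, 5 adjusted over the list alone, 5 at unadjusted p under 0.05; -0.95 without combination replicate 2) and smooth muscle (-0.28, 0 of 16 called, 0 adjusted over the list alone, 2 at unadjusted p under 0.05; -0.02 without dexamethasone replicate 1, -0.53 without replicate 2 and -0.23 without combination replicate 2). Fatty acid oxidation had 0.08 (0.16 and 0.21 without dexamethasone replicate 1 and 2, 0.18 and 0.05 without combination replicate 1 and 2; 0 of 29 called, 3 adjusted over the list alone, 7 at unadjusted p under 0.05; adjusted p = 0.359 with an estimated correlation). Smooth muscle had adjusted p = 0.694 with an estimated correlation, and the other 6 lists of this paragraph adjusted p = 0.495 with an estimated correlation. The goblet cell list (-0.22, 0 of 19 called, 3 at unadjusted p under 0.05, adjusted p = 0.12) and the Notch targets (-0.11, 9 of 9 lower, 0 called, 0 at unadjusted p under 0.05, adjusted p = 0.208) did not pass.

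**Figure D3:**
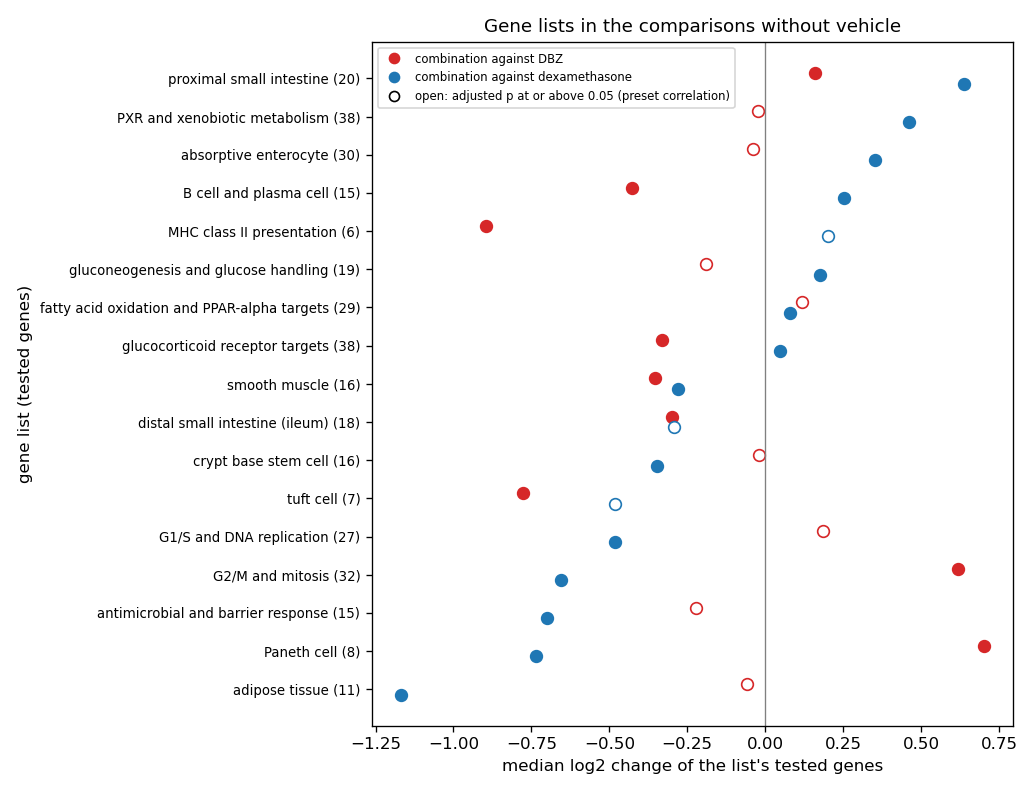
Median log2 change of gene lists in the combination against DBZ (red) and the combination against dexamethasone (blue), filled where the list passed with the preset correlation, with the number of tested genes in parentheses. The G2/M list lies at 0.62 against DBZ and at -0.65 against dexamethasone; with an estimated correlation 0 of 37 lists passed in either comparison.

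Limma called 4 of 13637 probe sets in the combination against dexamethasone, 3 higher and 1 lower (1265 at unadjusted p under 0.05), and 3 higher and 0 lower with quantile normalisation. It called 0 as deposited, with a pseudocount at the 5th percentile, without a filter, with a filter at the 60th percentile, without the intensity trend, without probe sets that may cross-hybridise and with a replicate block. It called 7 with robust moderation and 17 with array weights, with only the groups compared or without the vehicle arrays. Of 37 lists 14 passed with the preset correlation and 0 with the estimated correlation (camera; 3 at unadjusted p under 0.05). The count was 1 without dexamethasone replicate 1, 105 (21 higher and 84 lower) without dexamethasone replicate 2, 16 without vehicle replicate 1, 17 without vehicle replicate 2 and 0 without either combination array.

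The interaction asks whether the change with DBZ differs with dexamethasone. It was led by Fabp6 and Reg1, which separated vehicle from all treated arrays. Its largest positive values were Reg1 (6.29 ± 0.40, SE over 7 arrays), Cyp2c29 (5.86 ± 0.73), Max (4.56 ± 0.53), Akp3 (4.17 ± 0.91) and Bbox1 (3.64 ± 0.54). Its largest negative values were Fabp6 (-12.11 ± 0.62, adjusted p = 4.41e-05), Reg3g (-5.97 ± 0.98), Tmigd1 (-5.49 ± 0.40), Fam151a (-5.20 ± 0.62) and Mgat4c (-5.04 ± 0.58). The call of Akp3 ended without dexamethasone replicate 1 (3.55) or combination replicate 1 (4.08) or 2 (4.23), and without combination replicate 1 those of Bbox1 (3.31) and Reg3g (-5.58) ended. Of the 547 called probe sets, 546 were opposite in sign to the mean of treated minus vehicle, 532 were also called in DBZ or dexamethasone against vehicle, and 31 were called in a comparison that leaves vehicle out. Klf4 (-0.74 ± 0.34), Ccnd2 (-0.50 ± 0.38), Hes1 (0.13 ± 0.44), Atoh1 (-0.65 ± 0.40), Mki67 (0.52 ± 0.44), Fkbp5 (-0.20 ± 0.53), Tsc22d3 (-0.29 ± 0.45) and Nr3c1 (0.95 ± 0.26, adjusted p = 0.0768) did not pass.

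In the interaction the ileal list had -1.81 (9 of 18 fell, 11 and 1 higher adjusted over the list alone, list adjusted p = 1.29e-17, adjusted p = 0.601 with an estimated correlation). Pyy stood at -4.0 ± 0.45. The proximal list had 1.29 (10 of 20 rose, 11 and 1 lower adjusted over the list alone, list adjusted p = 2.55e-13) and the xenobiotic list 1.11 (15 of 38 rose, 22 and 1 lower adjusted over the list alone, list adjusted p = 1.65e-15), both with adjusted p = 0.144 with an estimated correlation; Hnf4g had 3.09 ± 0.40 and Slc46a1 3.43 ± 0.47. Smooth muscle had -1.51 (6 of 16 fell, 14 adjusted over the list alone), fibroblast -1.41 (5 of 29 fell, 18 and 1 higher adjusted over the list alone; Grem1 -2.35 ± 0.35), cholesterol synthesis -0.60 (0.37 as deposited; 4 of 19 fell, 5 adjusted over the list alone; Fdft1 -2.60 ± 0.30) and goblet cell -0.84 (0.11 as deposited; 1 of 19 fell, 4 adjusted over the list alone; Guca2a -2.34 ± 0.32). Fatty acid oxidation had 0.41 (1 of 29 rose, 5 adjusted over the list alone; 0.27 without dexamethasone replicate 2 or vehicle replicate 1, 0.20 without combination replicate 2), and for these 5 lists adjusted p = 0.601 with an estimated correlation.

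The last 5 lists past the threshold in the interaction each depended on single arrays. The G2/M list had 0.52 (1.39 as deposited; 28 of 32 higher, 0 called, 0 adjusted over the list alone, 7 at unadjusted p under 0.05 by limma; adjusted p = 0.669 with an estimated correlation) and no longer passed without vehicle replicate 1 (0.35) or combination replicate 2 (0.22); it had 0.98 without combination replicate 1. The enterocyte list had 0.20 (5 of 30 rose and 2 fell, 9 and 2 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation; 0.10 without dexamethasone replicate 1 and 0.14 without vehicle replicate 2, where it did not pass). It had 0.37 without dexamethasone replicate 2, 0.41 without combination replicate 1 and 0.09 without combination replicate 2. Apob stood at 3.37 ± 0.45. The urea cycle list had 0.44 (2 of 13 rose, 5 adjusted over the list alone; 0.37 without dexamethasone replicate 1 and 0.26 without vehicle replicate 2), and the adipose list -1.89 (1 of 11 fell, 4 adjusted over the list alone; -1.65 without combination replicate 2 and -0.80 without vehicle replicate 2), both with adjusted p = 0.624 with an estimated correlation. The interferon list had 0.58 (0 of 24 called, 0 adjusted over the list alone, 6 at unadjusted p under 0.05; adjusted p = 0.648 with an estimated correlation) and no longer passed without dexamethasone replicate 2 (0.31), vehicle replicate 1 (0.51) or combination replicate 1 (0.44) or 2 (0.61).

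Limma called 547 of 13637 probe sets in the interaction, 283 higher and 264 lower (2798 at unadjusted p under 0.05). With the intensities as deposited, where the median of all probe sets was 0.94, the split was 6450 higher and 117 lower. Without a filter 235 probe sets were called and without the intensity trend 208. Of 37 lists 13 passed with the preset correlation and 0 with the estimated correlation (camera; 2 at unadjusted p under 0.05). The count was 204 without dexamethasone replicate 1, 336 without vehicle replicate 2, 92 without combination replicate 1 and 186 (118 higher and 68 lower) without combination replicate 2.

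DBZ minus vehicle carries the difference of vehicle from all treated arrays, which combination minus dexamethasone leaves out. Their comparison therefore cannot show whether dexamethasone altered the DBZ change. The Pearson correlation across probe sets was -0.07 (Spearman -0.028), and -0.002 and -0.073 with replicate 1 and 2 arrays, which share the DBZ array. Over the 200 probe sets with the largest change on top of dexamethasone, selected in 1 replicate number and read in the other, the mean signed change was 0.65 there and -0.17 with DBZ alone. Their ratio divides by the small -0.17 and was -3.78 (-4.06 and -3.60 by replicate used). It ranged from -18.1 to -2.03 with single arrays left out and was 5.94 as deposited.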

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

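The tests of scaling, segment, batch, dim probe sets, exchanged labels and the segment for Fkbp5 were chosen only after the results were seen; the test of the DBZ array's quality was written before its value was computed, but the set of probe sets it uses was widened after a first value of 0.0654 had been seen.

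The interaction test flagged 547 probe sets whose change with DBZ differed between mice with and without dexamethasone. The named genes it flagged were Reg1 (6.29), Cyp2c29 (5.86), Max (4.56), Akp3 (4.17), Bbox1 (3.64), Fabp6 (-12.11), Reg3g (-5.97), Tmigd1 (-5.49), Fam151a (-5.20) and Mgat4c (-5.04). The difference between vehicle and every treated array enters this test and is weighed next.

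Vehicle arrays differed from all treated arrays in genes of intestinal position. A factor common to all probe sets of an array would leave the ileal and proximal lists together, but they stood apart by at least 1.546 after scaling, which excludes scaling as the whole cause. A difference in the segment sampled predicted that the lists would part by over 1 in each comparison, and the largest gap was 2.14, which is consistent with that explanation; the pattern was noticed before the test, so this is a hypothesis. A processing batch cannot be told apart from treatment, because 0 arrays carry the scaling target of the other side. A shared response to both drugs remains possible, and drug, segment and batch are confounded in these arrays.

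The calls of the combination against DBZ rest on 1 DBZ array with the highest 3' to 5' ratios. Poor quality of that array predicted that other probe sets of the called genes would change by less than 0.5 of the called change. The median ratio was 0.123 over 76 other probe sets, with 64.5% in the called direction, against 0.488, 0.667 and 0.593 in DBZ, dexamethasone and the combination against vehicle, although picking called probe sets lowers all such ratios. The called set was not dim (median signal percentile 60.84), but dimness stays open for single calls (Pigq, 9.4). The values suggest that many of these calls (ratio 0.123) belong to the array or to single probe sets, and an effect of dexamethasone is left open.

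Fkbp5 and Pdk4, which glucocorticoids induce, were lower in the dexamethasone arrays than in the vehicle arrays, while the list of receptor targets did not pass there (8 rose and 5 fell, adjusted p = 0.867). Exchanged labels would place the lymphocyte lists higher in those arrays; the B cell list was lower in both comparisons, but its larger adjusted p with an estimated correlation was 0.643. The T cell list was lower as well, by -0.76 in dexamethasone against vehicle (adjusted p = 0.00132) and by -0.24 in the combination against DBZ (adjusted p = 0.53), with adjusted p of 0.438 and 0.942 with an estimated correlation, so the question stays open. A difference in segment would make Fkbp5 in the DBZ array, whose ileal genes are high, as low as in the dexamethasone arrays. It was 1.72 ± 0.41 higher there by 1 probe set (SE, adjusted p = 0.117) and 0.99 ± 0.27 by the other (adjusted p = 0.141), and with 1 DBZ array the test stays open. Negative feedback on endogenous corticosterone, or sampling long after the last dose, are biological explanations that these arrays do not test.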

How the results depend on the processing

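Over all alternatives the 257 called results of named genes gave 4549 values, of which 4030 kept the call, 512 lost it and 7 reversed. Except where a smaller number of arrays or of tested probe sets is itself the alternative, the cause was not tested. Signal near background limits genes such as Fabp6 in the vehicle arrays, whose fold rests on the pseudocount.

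With the values as deposited, the vehicle arrays keep their higher scaling target, and the counts were 9516, 10403 and 11051 for DBZ, dexamethasone and the combination against vehicle, 8 for the combination against DBZ, 0 for the combination against dexamethasone and 6567 for the interaction. Medians that reversed were, in DBZ against vehicle, goblet cell (-0.46), glucocorticoid receptor targets (-0.62), cholesterol synthesis (-0.51), MHC class II (-0.088), immediate early (-0.43) and apoptosis (-0.86). In dexamethasone against vehicle they were goblet cell (-0.22) and cholesterol synthesis (-0.33). In the combination against vehicle they were goblet cell (-0.54), cholesterol synthesis (-0.54), smooth muscle (-0.11), fibroblast (-0.31) and immediate early (-0.57), and in the interaction goblet cell (0.11) and cholesterol synthesis (0.37). The lists that lost the call without reversing were T cell in the 3 comparisons against vehicle, antimicrobial and pancreatic in DBZ against vehicle, B cell and interferon in dexamethasone against vehicle, G2/M (-1.48) and antimicrobial in the combination against vehicle, and G2/M (1.39) and interferon in the interaction. The genes that reversed were Mcl1 (-0.0305), Casp8 (-0.17) and Cdkn1a (-0.16) with DBZ, Glul (-0.0834) with dexamethasone, and Ccnd2 (-0.0166), Clca1 (-0.0491) and Btg2 (-0.11) with the combination, and the ratio of the DBZ changes was 5.94.

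Quantile normalisation gave 6 calls in the combination against DBZ and 3 against dexamethasone, with a ratio of -2.31. A pseudocount at the 5th percentile gave 0 calls in the combination against dexamethasone, and the 40th percentile gave 10 against DBZ and a ratio of -3.31. Without a filter the counts were 540, 1079, 623, 5, 0 and 235 in the order above, and the ratio was -2.56. With a filter at the 60th percentile the combination against dexamethasone had 0 calls. The list calls lost with that filter were immediate early in DBZ against vehicle, Paneth and B cell in dexamethasone against vehicle, B cell in the combination against DBZ, Paneth cell in the combination against dexamethasone, and G2/M (0.52), enterocyte and interferon in the interaction. Without the intensity trend DBZ against vehicle had 684 calls, the combination against vehicle 659, against DBZ 0, against dexamethasone 0 and the interaction 208. The combination against dexamethasone had 7 calls with robust moderation, 17 with array weights and 0 without probe sets that may cross-hybridise. With only the groups compared, the combination had 207 calls (156 higher and 51 lower) against DBZ and 17 (11 and 6) against dexamethasone. Without the vehicle arrays the counts were 22 and 17. The ratio was -2.08 with 50 probe sets and -3.26 with 500. With both DBZ columns as separate arrays the counts were 4080, 2637, 1984, 1075, 8 and 2112, since a copied array adds no spread.

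Settings other than the deposited values and that filter ended the list calls of T cell, antimicrobial, apoptosis and pancreatic in DBZ against vehicle, of enterocyte, B cell and urea cycle in dexamethasone against vehicle, and of glucose handling in the combination against vehicle. They also ended those of B cell, tuft cell, Paneth cell and proximal in the combination against DBZ, of smooth muscle in the combination against dexamethasone, and of enterocyte, adipose and interferon in the interaction.

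Arrays with the same replicate number did not deviate together (correlations of 0.0488, -0.122 and 0.115), so the numbers do not pair the samples. With a replicate block the counts were 1491 in dexamethasone against vehicle, 892 in the combination against vehicle and 0 in the combination against dexamethasone. No paired analysis was possible because of the 1 DBZ array in the comparisons that use it.

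When 1 array was left out, the counts ranged from 700 to 989 in DBZ against vehicle, 572 to 1624 in dexamethasone against vehicle, 170 to 1015 in the combination against vehicle, 0 to 33 in the combination against DBZ, 0 to 105 in the combination against dexamethasone and 92 to 567 in the interaction. Without vehicle replicate 1 the split was 442 higher and 281 lower in DBZ against vehicle and 505 and 212 in the combination against vehicle. The antimicrobial median of DBZ against vehicle ranged from -0.33 to 0.22 and reversed without vehicle replicate 1 (0.22) or 2 (0.16). The G2/M median ranged from -0.91 to -0.24 in the combination against vehicle and from 0.22 to 0.98 in the interaction. The correlation of the DBZ changes ranged from -0.13 to -0.0033 and their ratio from -18.1 to -2.03.

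With an estimated correlation 0 lists passed in each of the 6 comparisons, while the medians stayed the same by construction. In DBZ against vehicle this applies to goblet cell (0.51), G2/M (-1.20), glucocorticoid receptor targets (0.34), smooth muscle (1.31) and ileum (1.46). In dexamethasone against vehicle it applies to goblet cell (0.73), xenobiotic metabolism (-0.999), proximal (-0.80) and ileum (1.35). In the combination against vehicle it applies to goblet cell (0.39), G2/M (-0.55), smooth muscle (0.88), fibroblast (0.62) and ileum (1.23), and against DBZ to G2/M (0.62), glucocorticoid receptor targets (-0.33) and MHC class II (-0.90). In the combination against dexamethasone it applies to enterocyte (0.35), G2/M (-0.65), glucocorticoid receptor targets (0.0486), xenobiotic metabolism (0.46) and proximal (0.64), and in the interaction to goblet cell (-0.84), G2/M (0.52), xenobiotic metabolism (1.11), proximal (1.29) and ileum (-1.81).

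Not run were the planned ratio that selects probe sets in 1 DBZ array and reads them in the other, the replicate block for comparisons with DBZ, the removal of 1 DBZ copy, and the list tests with only the groups compared.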

Other observations

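The genes in this part were chosen only after their values were seen.

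Between the dexamethasone arrays 357 probe sets differed over 2-fold, against 465 between the vehicle arrays and 234 between the combination arrays. The carbonic anhydrase Car1 had a signal of 7460 in replicate 1 and 40.2 in replicate 2, with 1.78 and 4.11 in the vehicle arrays. In the same order Saa1 had 1660, 12.2, 3.10 and 1.47, Slc6a14 had 648, 8.96, 2.33 and 18.1, and Mal had 296, 1.46, 2.47 and 8.16. Cyp2c55 (6324, 150, 2818 and 1029) and Car2 (2138, 55.3, 577 and 658) were also high in the vehicle arrays.

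Of 8 glucocorticoid-induced genes compared between the DBZ array and the dexamethasone arrays, 1 passed. Pdk4 was 2.38 ± 0.30 higher in the DBZ array (SE, adjusted p = 0.0354). Zbtb16 (2.30 ± 0.40, adjusted p = 0.0553), Klf15 (2.24 ± 0.45, adjusted p = 0.0765), Tsc22d3 (1.64 ± 0.35, adjusted p = 0.0897) and Fkbp5 (1.72 ± 0.41, adjusted p = 0.117) did not pass, nor did Cebpd (1.13 ± 0.32, adjusted p = 0.148), Klf9 (0.65 ± 0.30, adjusted p = 0.34) and Per1 (0.42 ± 0.31, adjusted p = 0.553). Other probe sets gave 0.99 for Fkbp5, 0.90 and 0.16 for Tsc22d3, and -0.31 to 0.73 for Klf9, and none passed.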
